A study of Mus musculus with 4 samples.

How the data were processed

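The data are RNA-seq counts from lung γδ T cells of Aire-/- and Aire+/+ mice, 2 libraries per genotype, made from 500 sorted cells each by Smart-Seq2, per the labels' protocols. The authors deposited 1 table of whole-number read counts per gene symbol with 1 column per library, per the file headers. Library totals differed and no normalization was applied to these deposited counts as far as the values show. TopHat2 2.0.10, Cufflinks 2.2.1 and the mouse build mm10 are named, without role or order, per the submitters' processing notes. How reads were assigned to genes, the gene annotation, the handling of strand, of reads shared between similar genes and of PCR duplicates are not given in the sources used here. Smart-Seq2 carries no molecular identifiers in its original form, so reads are not independent molecules, and intervals and floors cover counting error only. Reads from a gene and from a partner on the opposite strand cannot be told apart in such counts.

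Groups were taken from the genotype label. Counts were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1, DESeq2 1.42.0), with TMM normalization, filterByExpr (minimum count 10, minimum total 15), quasi-likelihood F tests on genotype alone and Benjamini-Hochberg adjustment, all 4 libraries entering the fit. This left 9783 of 22865 genes, and a gene was called at an adjusted p under 0.05. Means ± SD are of CPM scaled by the TMM factors, and a log2 fold change is Aire-/- minus Aire+/+ from the edgeR fit. Its SE is approximate, being the absolute log2 fold change divided by the square root of the F statistic, and is not reported by edgeR. Means and SDs use counts of 0 as they are. Only where all libraries of a genotype were at 0 was a limit of 3 counts used, per library for Aire and over the pair for the bound on Cd14. Depths ran from 1106891 to 1265239 counts per library, at which genes of a few counts fell below the filter and were not tested.

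A total of 27 gene lists were fixed before the data were examined, as were the test, the named-gene rule and most alternatives. The lists cover the T17 program, T cell receptor signalling, type 1 and cytotoxic genes, cytokines and growth factors, cytokine and chemokine receptors, costimulatory and inhibitory receptors, residency, immediate early genes, glycolysis, oxidative phosphorylation, sterol and fatty acid genes, cell cycle, the interferon response, heat shock, ribosomal proteins, and markers of other cells the lung or the gate could hold. Lists with at least 5 tested members were tested with limma's camera on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the lists. The 6 lists with fewer were neutrophil, mast cell and basophil, lung epithelial, endothelial, fibroblast and smooth muscle, and red cell and platelet markers. Of 40 T17 genes 12 of the 35 tested also stand in another list. The named genes are Aire, those past the threshold, the next up to 5 by p in each direction, a fixed set of T17 genes, and up to 4 members with the smallest p in each list. Genes named outside that rule are said to be picked after their values were seen, and Ms4a1, Cd79a and Cd79b on 1 side and the CD3 chains on the other serve as marker sums, Cd4, Cd8a and the sex-linked genes as checks of the labels, and Rn45s as the measure of ribosomal RNA. Some members of the lists are not reported here by name, although they are counted in the lists.

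Gene coordinates and current symbols came from the RefSeq annotation of GRCm38, the assembly that mm10 names, which matched 22709 symbols. Transcript length and GC content, taken from the longest transcript of each gene, and overlapping genes came from GENCODE M21. Alternatives were DESeq2 or upper-quartile size factors, DESeq2's Wald test, limma-voom, no filter beyond a count above 0, a stricter filter (10 CPM in 2 libraries), robust dispersion, an adjusted p of 0.1, the replicate number as a block, each library left out in turn, and for lists an estimated correlation and fry. Rn45s left out, the trend with length and GC content removed (loess span 0.5), and a list background without B cell, dendritic cell and macrophage genes were added after seeing the data. The steps were tested on 20 simulated data sets with 200 changed genes. Calculations in Python used version 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.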

Results

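RNA was sequenced from γδ T cells sorted from the lungs of 10-week-old female C57BL/6 mice that lacked Aire or carried it. Aire is the transcriptional regulator that lets medullary thymic epithelial cells display tissue-restricted proteins to developing T cells. The sorted cells were viable, positive for CD45 and the γδ T cell receptor, and negative for TCRβ, CD27 and 4 other Vγ chains. The submitters call this population Tgd17, the γδ T cells that produce interleukin-17. Each library was made from 500 cells by Smart-Seq2, a full-length cDNA method for very small samples, with 2 libraries from Aire-/- and 2 from Aire+/+ mice. The count table held 22865 gene symbols, of which 2463 had no count in any library. Total counts were 1144060 and 1106891 in the Aire-/- libraries and 1265239 and 1153344 in the Aire+/+ libraries, and 16283 to 17423 genes had at least 1 count. The labels do not say that the libraries came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. Libraries of 1 genotype were not copies of each other, since their counts differed by a chi-square per degree of freedom of 4.1 in Aire-/- and 4.0 in Aire+/+, against 3.72 to 5.66 between genotypes.

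Aire itself (chromosome 10, 78030022 to 78043610, GRCm38) had 0 counts in all 4 libraries. A count of 0 allows up to 3 counts, which is 2.62 and 2.71 CPM (the count scaled to a common library total) in the Aire-/- libraries and 2.37 and 2.60 CPM in the Aire+/+ libraries. The targeted gene therefore checked no genotype label. Cd4, the helper T cell co-receptor, had 2 to 5 counts per library, Cd8a had 25 to 35, and Cd27, which the sort excluded, had 5 to 15. Xist, the RNA of the silenced X chromosome, had 1371 to 1629 counts. Of the Y-linked genes, Kdm5d and Eif2s3y had 0 counts in all 4 libraries, Ddx3y had 2 to 11 and Uty 6 to 15. Of 27 γδ receptor gene segments sought, 0 stood in the count table, and the immunoglobulin constant genes were not analysed here.

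The question the design poses is how loss of Aire alters gene expression in these peripheral cells. Igj was nearly absent from Aire-/- libraries and abundant in Aire+/+ libraries, at 1.89 ± 2.67 against 1030 ± 456 CPM (SD, n = 2 each). Igj, now named Jchain, encodes the joining chain that links polymeric IgA and IgM in antibody-secreting cells. Cpm, a membrane carboxypeptidase that trims C-terminal arginine and lysine from peptides, was 3.64-fold lower in Aire-/- libraries, at 53.4 ± 4.48 against 195 ± 10.4 CPM (SD, n = 2 each). The defining genes of the interleukin-17 program were expressed in both genotypes, and none passed the test over all genes. By limma's camera with its preset correlation, the T17 list lay slightly higher and the B cell and macrophage lists lower in Aire-/- libraries. None of these 3 lists was called with the correlation estimated, at an adjusted p = 0.49 with an estimated correlation for each. On simulated libraries that version called a T17 list shifted by 0.5 on the log2 scale in 0 of 20 simulations. A miss by it therefore does not tell a shift from none at this sample size.

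**Figure D1:**
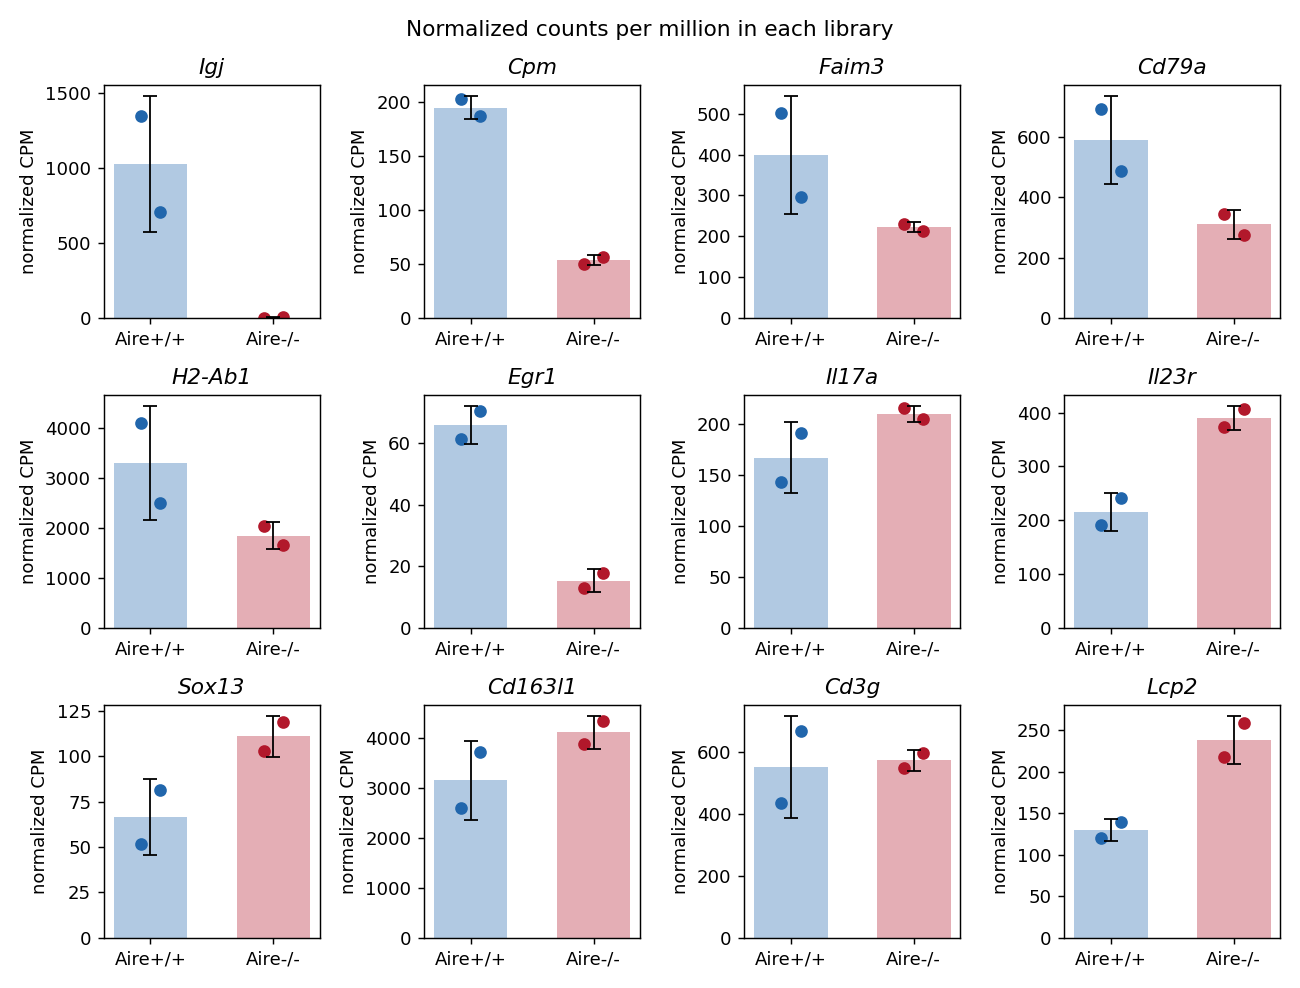
Normalized CPM (y axis, linear, from 0) of 12 genes in each library, with Aire+/+ in blue and Aire-/- in red; points are libraries, bars are group means and error bars are the SD (n = 2). Igj and Cpm passed the test over all genes, and Igj stood at 0 and 3.77 CPM in the Aire-/- libraries against 1350 and 708 CPM in the Aire+/+ libraries.

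Of 9783 genes tested, edgeR's quasi-likelihood test called 0 higher and 2 lower in Aire-/- libraries at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 274 higher and 271 lower genes, 545 in all, where chance gives 489. DESeq2's Wald test called 0 higher and 4 lower, and limma-voom 0 higher and 1 lower. Both Aire-/- values lay above both Aire+/+ values for 1671 genes and below them for 1693, together 34.4% of genes, where chance gives 33.3%. Log2 CPM across genes correlated between libraries of the same genotype with a mean Pearson r of 0.918, and between genotypes with 0.916, genes being no independent replicates. Counts of calls moved with single libraries. Genes called higher numbered 13 without Aire-/- replicate 1, 5 without Aire-/- replicate 2, 6 without Aire+/+ replicate 1 and 21 without Aire+/+ replicate 2, and genes called lower 9, 12, 6 and 42 in the same order. In those fits the lone library of a genotype is assumed to vary like the pair of the other. On simulated libraries of this design with 9408 genes tested, the test recovered 73.2% of 4-fold and 21.2% of 2-fold changes, and 5.7% of its calls were false.

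Igj lies on chromosome 5 (88519809 to 88527897, GRCm38, ENSMUSG00000067149), is protein-coding and overlaps no other annotated gene. Its counts were 0 and 4 in the Aire-/- libraries and 1674 and 827 in the Aire+/+ libraries. The fitted log2 fold change was -9.03 (SE 0.55, adjusted p = 8.1e-06, edgeR), with all 4 libraries in that direction. Scaled to library size, the Aire+/+ to Aire-/- ratio of the summed Igj counts was 560, with a 95% exact Poisson interval of 218 to 2060 that covers counting error only. Only limma-voom did not call Igj, with an adjusted p of 0.32 at a log2 fold change of -9.46, while its adjusted p lay between 8.9e-141 and 3.3e-04 under every other alternative tried. Cpm lies on chromosome 10 (117629500 to 117687352, GRCm38, ENSMUSG00000020183), 39.6 Mb from Aire, and a small nuclear RNA gene, Gm25709, overlaps it on the opposite strand. Cpm had 55 and 60 counts in Aire-/- and 250 and 219 in Aire+/+ libraries, a log2 fold change of -1.86 (SE 0.24, adjusted p = 0.017, edgeR), and stayed past the threshold under every alternative tried.

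The next genes in order of p did not pass over all genes. On the lower side, Bcat1, the cytosolic aminotransferase of branched-chain amino acids, stood at 3.74 ± 2.71 against 46.1 ± 20.5 CPM (log2 fold change -3.60, SE 0.59, adjusted p = 0.14). Egr1, an immediate early transcription factor induced by receptor signalling, stood at 15.4 ± 3.63 against 65.8 ± 6.18 CPM (-2.09, SE 0.36, adjusted p = 0.19). Cd74, the invariant chain of class II molecules, had a log2 fold change of -0.96 (adjusted p = 0.35) and B3gnt7, a glycosyltransferase, one of -2.59 (adjusted p = 0.58). Cd14, the lipopolysaccharide co-receptor of monocytes, had 0 counts in both Aire-/- libraries and 32 and 11 in the Aire+/+ libraries, which is at least 12.8-fold lower with 3 counts allowed over the pair (adjusted p = 0.45). On the higher side, Ptgs2, the inducible cyclooxygenase, stood at 83.9 ± 30.8 against 20.9 ± 5.55 CPM (2.00, SE 0.37, adjusted p = 0.30). Nav2 (1.16), Cysltr2, a receptor for cysteinyl leukotrienes (2.60), Sytl1 (1.17) and Vwa5a (1.53) followed, with adjusted p from 0.35 to 0.58 by edgeR. DESeq2 placed Bcat1 at an adjusted p of 0.050 and Cd74 at 0.049, where the range over all alternatives ran down to 8.1e-07 for Bcat1 and 3.4e-05 for Cd74.

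The interleukin-17 machinery was present in both genotypes. Il17a, the cytokine that names the subset, stood at 211 ± 8.38 CPM in Aire-/- and 167 ± 34.4 CPM in Aire+/+ libraries (SD, n = 2 each; log2 fold change 0.33, SE 0.22, adjusted p = 0.94). Il23r, the receptor for the interleukin-23 that sustains these cells, stood at 390 ± 23.2 against 216 ± 35.8 CPM (0.85, SE 0.20, adjusted p = 0.61). Cd163l1, a scavenger receptor of γδ T cells also known as Scart1, was the most abundant gene of this group at 4120 ± 329 against 3160 ± 791 CPM (0.38, adjusted p = 0.89). Log2 fold changes of further fixed T17 genes were 0.74 for Sox13, 0.58 for Il1r1, 0.51 for Maf, 0.38 for Ccr6, 0.21 for Rora, 0.15 for Blk and 0.12 for Il17f, with adjusted p of 0.89 or more. The libraries also held B cell transcripts, and the cells that carried Ccr6 and Blk were not told apart. The related scavenger receptor Scart2, listed as 5830411N06Rik, had 53 and 3 counts in Aire-/- and 22 and 12 in Aire+/+ libraries (0.87, SE 0.81). Il22 (0 to 5 counts), and Ifng (1 to 3 counts) and Tbx21 (0 to 7 counts), the cytokine and lineage factor of type 1 cells, were too low to test.

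Of the 35 tested members of the T17 list, 32 lay above 0 and the median log2 fold change was 0.34. Camera called the list higher against other genes (adjusted p = 1.7e-04, limma), and it was not called at an adjusted p = 0.49 with an estimated correlation. Il23r alone passed when adjusted over the list alone (adjusted p = 0.039), and 0 members passed over all genes. Kcnk1, a potassium channel (1.12), and Sox13 (0.74) had the next smallest p after Il23r. The call rested on Aire+/+ replicate 1, without which its adjusted p was 0.20. Of 21 T cell receptor and proximal signalling genes 19 lay above 0, with a median log2 fold change of 0.21 against 0.34 for the T17 list, and a mean of 0.32 against 0.34. Camera called this list higher (adjusted p = 0.0020), against an adjusted p = 0.49 with an estimated correlation, and the call was lost without Aire-/- replicate 2 (0.094) and without Aire+/+ replicate 1 (0.12). Lcp2, the adaptor SLP-76, rose by 0.89 when adjusted over the list alone (adjusted p = 0.030), with 0 members passing over all genes. Zap70 (0.46) and Cd5 (1.13) did not pass. In the same libraries B cell markers moved the other way, as given with the B cell list.

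In the interferon list, 21 of 27 members lay above 0, with a median log2 fold change of 0.43. Camera called it higher (adjusted p = 3.5e-04), against an adjusted p = 0.49 with an estimated correlation and 0.22 without Aire-/- replicate 2. Adjusted over the list alone 4 members rose and 0 passed over all genes, and among the 4 were Ifi47 (1.21), Irgm1 (1.07) and Gbp2 (1.12). These are GTPases that interferon-γ also induces strongly. In the same libraries T cell receptor genes lay higher and B cell markers lower, and a shift in mixture was not tested for the interferon list. Irf7, the amplifier of type I interferon production, had a log2 fold change of 0.09 and the ubiquitin-like Isg15 one of -0.40, both picked after their values were seen. The interferon-γ receptor chain Ifngr1 stood at 1740 ± 479 against 937 ± 259 CPM (0.89). Ifngr1 and Il23r passed adjusted over the list alone within the cytokine and chemokine receptors (adjusted p = 0.028 for both), where 20 of 32 members lay above 0 and the list was not called (camera adjusted p = 0.15).

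**Figure D2:**
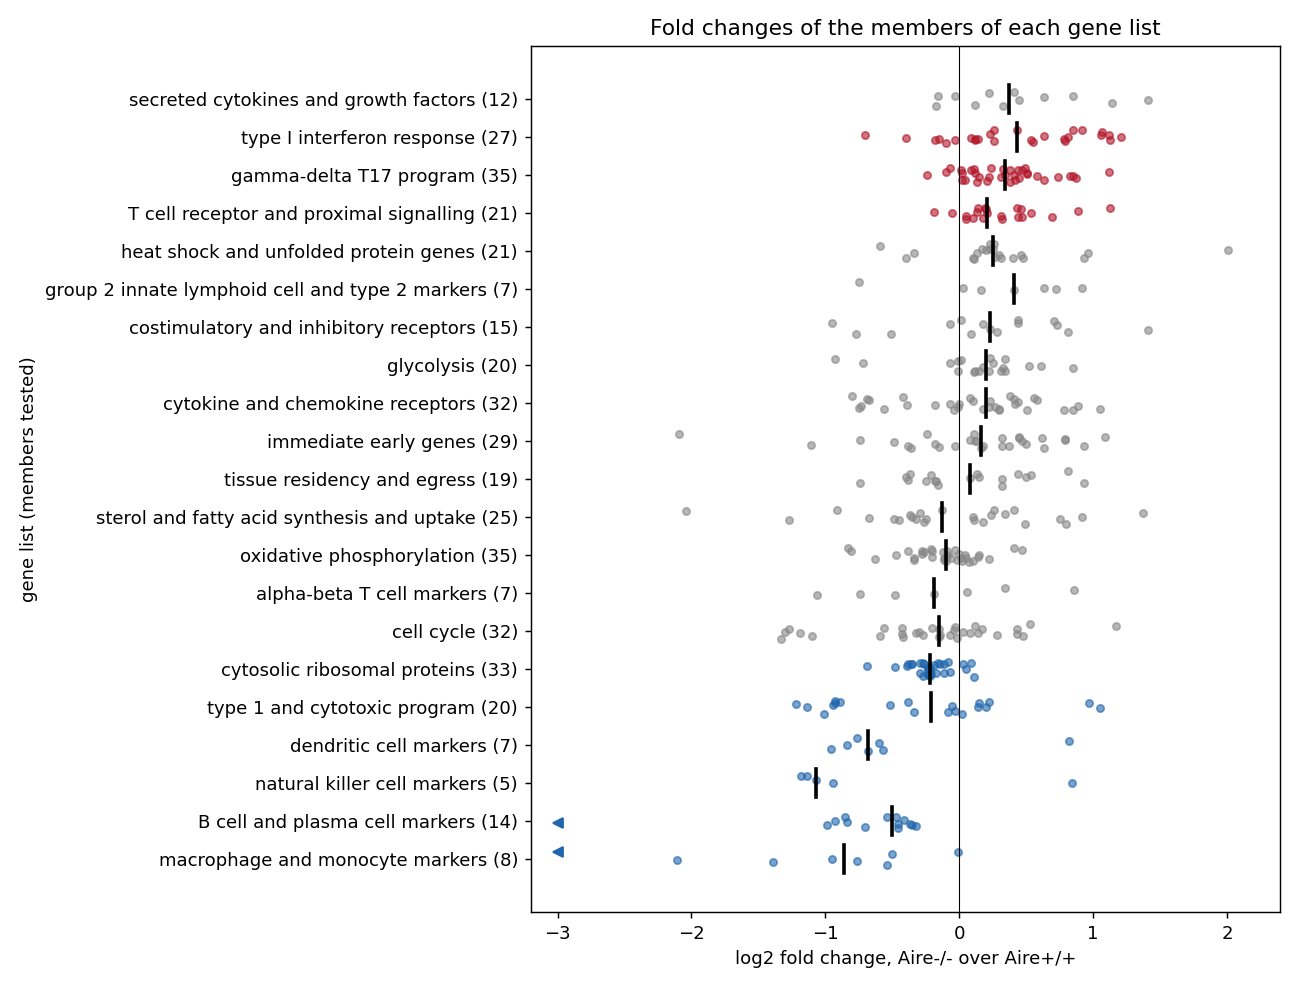
Log2 fold change (x axis, Aire-/- over Aire+/+) of each tested member of 21 gene lists (y axis, number tested in parentheses); black bars are list medians, and red or blue lists were called higher or lower by camera with the preset correlation. Igj and Cd14, both below -3, are drawn as arrowheads, and with an estimated correlation 0 lists were called.

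Transcripts of B cells, which the gate was meant to exclude, were abundant in all 4 libraries and lower in the Aire-/- pair. Cd79a, a signalling chain of the B cell receptor, stood at 310 ± 49.4 against 589 ± 146 CPM, and Faim3, the Fc receptor for IgM now named Fcmr, at 223 ± 12 against 399 ± 144 CPM (SD, n = 2 each). All 14 tested members of the B cell and plasma cell list lay below 0, with a median of -0.50. Camera called the list lower (adjusted p = 8.7e-07), and it was not called at an adjusted p = 0.49 with an estimated correlation. Adjusted over the list alone 5 members fell, Igj, Cd79a (-0.93), Faim3 (-0.84), Mzb1 (-0.99) and Fcer2a (-0.70, named after its value was seen), and over all genes 1, Igj. Libraries of the same genotype differed. Summed counts of Ms4a1, Cd79a and Cd79b were 0.985 and 0.681 times those of the CD3 chains in the Aire-/- libraries, against 2.08 and 0.873 times in the Aire+/+ libraries, so Aire+/+ replicate 2 lay between the Aire-/- libraries. Camera's call included Igj, and the list was not tested without it. Its mean log2 fold change was -1.19 with Igj and -0.59 over the other 13 members. Against Aire+/+ replicate 1, those 13 differed by -0.71 and -1.05 on average in Aire-/- replicates 1 and 2. Against Aire+/+ replicate 2 they differed by only -0.07 and -0.41.

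Genes of antigen-presenting cells were lower too. In the dendritic cell list 6 of 7 members lay below 0 (median -0.68), and the 4 that fell when adjusted over the list alone were class II genes that B cells also express: Cd74 (-0.96), H2-Ab1 (-0.84), H2-Aa (-0.76) and H2-Eb1 (-0.68), with 0 over all genes. Xcr1, a receptor of cross-presenting dendritic cells, had a log2 fold change of 0.82, picked after its value was seen. Camera called the list lower (adjusted p = 0.015), against an adjusted p = 0.49 with an estimated correlation, and it was lost without Aire-/- replicate 1 (0.063), Aire-/- replicate 2 (0.35) or Aire+/+ replicate 1 (0.50). All 8 tested macrophage and monocyte genes lay below 0, with a median of -0.86 that is the same with Cd14 at its bound. Single libraries set some of these values: Lyz2, the lysozyme of myeloid cells, named after its values were seen, had 1 and 61 counts in Aire-/- and 186 and 2 in Aire+/+ libraries, and was called higher without Aire+/+ replicate 1 (4.00, adjusted p = 0.017) and lower without Aire-/- replicate 2 (-6.24) or Aire+/+ replicate 2 (-2.37). Cd14 was the 1 member that passed adjusted over the list alone, with 0 over all genes. Mrc1, the mannose receptor (-2.11), Apoe, a lipid carrier (-0.95), and Ctss, a lysosomal protease (-0.54), did not pass. Camera called this list lower (adjusted p = 3.5e-04), against an adjusted p = 0.49 with an estimated correlation and 0.92 without Aire+/+ replicate 1.

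**Figure D3:**
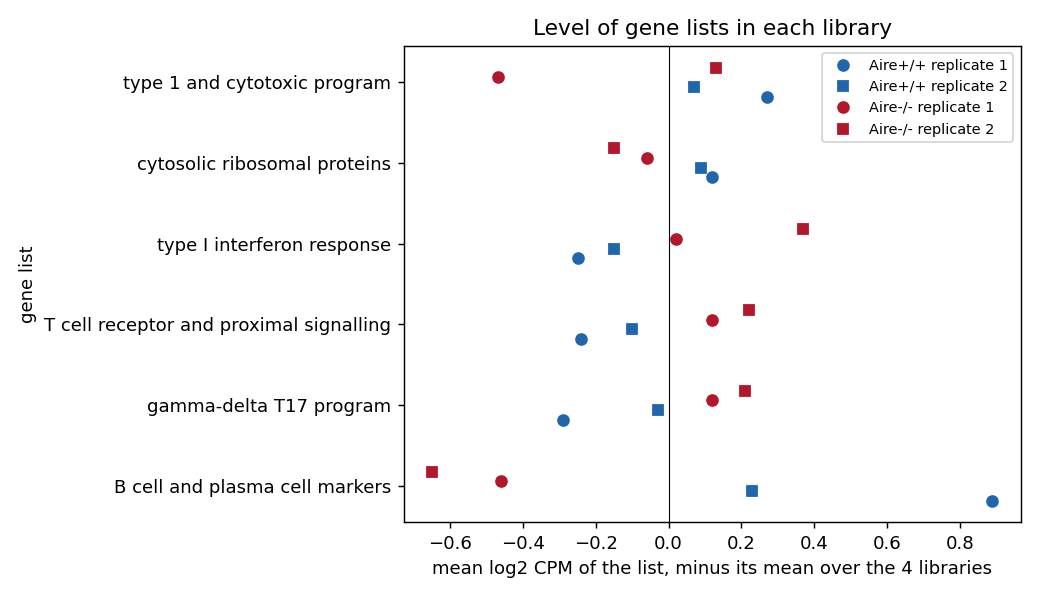
Mean log2 CPM of the members of 6 gene lists in each library (x axis), minus the mean over the 4 libraries; circles are replicate 1, squares replicate 2, Aire-/- is red and Aire+/+ blue. The B cell list, Igj included, spans -0.65 to 0.89 with Aire+/+ replicate 1 at the top. It stands at -0.46 in Aire-/- replicate 1 and 0.23 in Aire+/+ replicate 2, where its members other than Igj differ by -0.07 on average. The T17 list runs from -0.29 in Aire+/+ replicate 1 to 0.21 in Aire-/- replicate 2.

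Cytotoxic genes leaned lower in Aire-/- libraries. Adjusted over the list alone, Ccl5, a chemokine of cytotoxic lymphocytes (-0.93), and Nkg7, a cytotoxic granule protein (-1.22), fell within the type 1 and cytotoxic program, with 0 members over all genes. The granzymes Gzma (-0.94) and Gzmb (-0.89) did not pass, and 13 of 20 members lay below 0 (median -0.21). Camera called the list lower (adjusted p = 0.019), against an adjusted p = 0.49 with an estimated correlation, and it was lost without Aire-/- replicate 1 (0.90), Aire+/+ replicate 1 (0.63) or Aire+/+ replicate 2 (0.10). Among natural killer cell markers 4 of 5 lay below 0 (median -1.07) and 0 passed adjusted over the list alone or over all genes, with Itga2 at -1.18 and Klrb1c at -1.14. Camera called them lower (adjusted p = 0.028), against an adjusted p = 0.49 with an estimated correlation. That call was lost without Aire+/+ replicate 1 (0.63) or Aire+/+ replicate 2 (0.23), and the direction turned without Aire-/- replicate 1 (0.87). The αβ T cell markers were not called (4 of 7 below 0, adjusted p = 0.41), with Ccr7, the lymph node homing receptor, at -0.74. Which of the cells in the libraries carried Ccr7 was not tested.

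Among genes of early activation, Egr1 fell when adjusted over the list of immediate early genes alone (adjusted p = 0.0022), while Rgs1 (0.93), Dusp1 (1.09) and Gadd45b (0.79) did not pass, and 19 of 29 members lay above 0 with no call (adjusted p = 0.32). Sterol and fatty acid genes lay above 0 for 12 of 25 members (adjusted p = 0.56). None of them passed adjusted over the list alone, with Sqle, the squalene epoxidase, at -2.04, Mvd, a mevalonate pathway enzyme, at 1.37, Scd1 at -0.67 and Fasn, the fatty acid synthase, at 0.75. Cytosolic ribosomal protein genes were lower for 29 of 33 members (median -0.22). Camera called them lower (adjusted p = 0.0022), against an adjusted p = 0.49 with an estimated correlation, 0.16 without Aire-/- replicate 2, 0.12 without Aire+/+ replicate 1 and 0.24 once the trend with transcript length and GC content was removed. The ribosomal RNA precursor Rn45s took 20.35% (Wilson 95% interval 20.28 to 20.43) and 19.36% (19.28 to 19.43) of counts in the Aire-/- libraries, and 17.39% (17.32 to 17.45) and 16.24% (16.17 to 16.31) in the Aire+/+ libraries, intervals that cover counting error only.

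The other lists were not called by camera. Secreted cytokines and growth factors had 9 of 12 members above 0 (adjusted p = 0.051), led by Tnfsf11, the cytokine RANKL (1.41). They came past it without Aire-/- replicate 1 (0.011) or Aire+/+ replicate 1 (0.045), with the replicate block (0.043), the stricter filter (0.048), Rn45s left out (0.049) or the length and GC trend removed (0.011), and were at 0.45 without Aire-/- replicate 2, 0.10 without Aire+/+ replicate 2 and 0.49 with the correlation estimated. Glycolysis genes lay above 0 for 15 of 20 members (adjusted p = 0.14), with Pgk1 at 0.52 and Hk2 at 0.85. Oxidative phosphorylation genes lay below 0 for 23 of 35 (adjusted p = 0.15), with Ndufb10 at -0.81. Heat shock genes lay above 0 for 18 of 21 (adjusted p = 0.11), and 1 member rose when adjusted over the list alone with 0 over all genes, the chaperone Hsph1 (0.96), named after its value was seen. Group 2 innate lymphoid markers had 6 of 7 above 0 (adjusted p = 0.15), among them the tissue repair factor Areg (0.63). Costimulatory and inhibitory receptors had 11 of 15 above 0 (adjusted p = 0.23). The inhibitory receptor Btla fell by 0.95 when adjusted over the list alone (adjusted p = 0.031) with 0 over all genes. Which cells carried Btla was not tested, and B cell markers were lower in the same libraries. Tissue residency genes split 10 to 9 (adjusted p = 0.46), with Bhlhe40 at 0.81. Cell cycle genes lay below 0 for 21 of 32 (adjusted p = 0.30), with the mitotic kinesins Kif11 at -1.30 and Kif20a at 1.17, and were called lower only without Aire+/+ replicate 2 (0.039).

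Of the 21 lists tested, camera called 3 higher and 6 lower with its preset correlation, and 0 with an estimated correlation. Fry, which asks whether a list moves one way on balance, called 0, and its mixed version, which asks whether members move either way, called 2, the sterol and fatty acid list (adjusted p = 0.035) and the immediate early genes (adjusted p = 0.050). Counted list by list, 23 members passed adjusted over the list alone, with Il23r counted in both of its lists, and Igj passed over all genes. On simulated libraries the preset version called a T17 list shifted by 0.5 on the log2 scale in 20 of 20 simulations and the estimated version in 0 of 20. Those simulations drew genes independently. The estimated correlation between members was instead 0.80 for the B cell, 0.59 for the macrophage, 0.47 for the dendritic cell and 0.31 for the T17 list. It was 0.19 for the interferon and 0.18 for the ribosomal list. These called lists lay above the preset 0.01 that their camera p-values assume. The estimate was 0.01 for the T cell receptor list, 0.04 for the type 1 and cytotoxic list and -0.11 for natural killer markers. The estimated version thus lost called lists of high and of low correlation alike.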

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

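The tests without Rn45s, with the length and GC trend removed and with B cell, dendritic cell and macrophage genes left out of the background were chosen only after the results were seen, and left each count of calls within 1.5 times its value. In the last of these, the B cell, dendritic cell and macrophage lists were themselves not tested, which alone lowered the number of called lists. With the trend removed, camera lost the ribosomal list (adjusted p = 0.24) and called secreted cytokines (adjusted p = 0.011). Against 0 genes higher and 2 lower in Aire-/- libraries, no low-count filter gave 21 and 26, DESeq2's Wald test gave 0 and 4, and limma-voom 0 and 1. With replicate number as a replicate block, 2 genes were called higher and 4 lower, and 38 list members against 23 (a gene in several lists counts in each). Deviations of libraries with the same number correlated at -0.08 across genes, so nothing shows that the numbers pair the libraries. Without a filter 65 list members were called. Leaving out 1 library at a time gave 5 to 21 genes higher, 6 to 42 lower, 15 to 73 list members and 4 to 8 lists, against 9 lists with all libraries. An estimated correlation and fry each left 0 lists. Some genes that did not pass turned direction with 1 library left out. Their log2 fold changes then ran from -0.35 (without Aire+/+ replicate 2) to 0.84 for Il17f, from -0.11 (without Aire+/+ replicate 1) to 0.63 for Rora, from -0.03 (without Aire-/- replicate 2) to 0.31 for Blk, from -0.07 (without Aire+/+ replicate 1) to 2.47 for Calca, which passed at that value without Aire+/+ replicate 2 (adjusted p = 0.023), and from -2.26 (without Aire-/- replicate 1) to 1.77 for Scart2 (5830411N06Rik), which limma-voom put at -0.11. Cd27 ran from -0.93 (without Aire-/- replicate 1) to 0.58 and was also below 0 without Aire+/+ replicate 2 (-0.19), with upper-quartile factors (-0.02), by limma-voom (-0.13) and with the replicate block (-0.07). Lists that turned had adjusted p, over the libraries left out, of 0.18 to 0.92 for αβ T cell markers, 0.18 to 0.93 for costimulatory receptors, 0.073 to 1 for cytokine receptors and 0.57 to 0.93 for group 2 innate lymphoid markers, which were at 0.91, 0.91, 1 and 0.82 when they turned without Aire-/- replicate 2. Costimulatory receptors also turned without Aire+/+ replicate 1 (0.93), as did tissue residency (0.93, range 0.23 to 0.93). Without Aire-/- replicate 1, natural killer markers (0.87, range 0.0062 to 0.87) and sterol genes (0.87, range 0.29 to 0.97) turned, and immediate early genes (0.95, range 0.37 to 0.95) without Aire+/+ replicate 2. The cause was not tested for any of these. Among the values for named genes under alternatives, 1242 kept direction and side of the threshold, 64 came past it, 1 lost it and 11 turned. For lists these numbers were 199, 7, 34 and 9. Of the named genes only Igj and Cpm were called in the main fit. For the others, keeping their side of the threshold meant staying uncalled, so the 1242 is no measure of robustness. Alternatives written for values other than counts do not apply to this table. At this depth Il22, Ifng and Tbx21 stayed under the limit of testing, and on simulated data most 2-fold changes were missed.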

Other observations

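All tests of a smaller B cell share were chosen only after the result was seen, and for Cpm the comparison by library replaced a stricter bound that had left this share open, while those of plasma cells, of length and GC content and of strain variants near Aire were fixed before their results were seen. The 6 lists with too few tested members gave low sums in both genotypes. Summed counts in Aire-/- replicates 1 and 2 and Aire+/+ replicates 1 and 2 were 127, 153, 133 and 125 for neutrophil markers, 25, 27, 62 and 39 for mast cells and basophils, and 46, 32, 61 and 59 for lung epithelium. They were 241, 213, 304 and 354 for endothelium, with Pecam1, an adhesion molecule that leukocytes also carry, as its highest gene (named after its values were seen), 137, 94, 121 and 143 for fibroblasts and smooth muscle, and 29, 26, 57 and 28 for red cells and platelets. Enough endothelial markers passed the filter to be tested when a library was left out, and camera called them lower in Aire-/- without Aire+/+ replicate 1 (adjusted p = 0.049), but not without Aire-/- replicate 1 (0.75) or Aire-/- replicate 2 (0.75). By contrast the 3 B cell genes Ms4a1, Cd79a and Cd79b summed to 1499, 1086, 2583 and 1564 counts, against 1522, 1595, 1242 and 1791 for the CD3 chains, although the sort required the γδ receptor. Whether these transcripts came from B cells that passed the gate, from cells sorted as pairs or from free RNA was not tested, so a B cell share below means the share of such RNA.

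The near loss of Igj in Aire-/- libraries was larger than a smaller B cell share allows, since from its summed 4 counts in the Aire-/- libraries its log2 ratio was -9.13, where the lowest other B cell marker, Mzb1, less 3 SD gives -1.70. Fewer plasma cells, which the sort would also remove, stay open as a candidate explanation. Of 16 plasma cell genes fixed before that test 13 could be tested, and their median log2 change of -0.16 lay at percentile 4.67 of 10000 random lists matched on expression, with 9 of 13 below 0 (members named here were picked after their values were seen). This is weak, since Txndc5 (-1.01), Sec11c (-0.48) and Irf4 (-0.49) had the smallest p and B cells or T cells express several members. Sdc1 (0.29, 255 ± 68.7 against 209 ± 70.7 CPM) and Xbp1 (0.10) lay above 0. Sdc1 had 226 and 322 counts in the Aire-/- libraries, where Igj had 0 and 4. The cells that carried Sdc1 were not told apart, so its value does not measure the plasma cell share. Of the 3 genes too low to test, Tnfrsf17 had 0 and 1 counts in Aire-/- and 0 and 2 in Aire+/+ libraries. Derl3 had 4 and 2 against 3 and 9, and Fkbp11 0 and 0 against 3 and 5. An effect of genotype on Igj itself stays open too, as untested.

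The lower B cell list and the higher T17 list may be sides of 1 mixture, which the values leave open. The 13 B cell genes other than Igj had log2 changes from -0.99 to -0.32 with an SD of 0.24, but this lay at percentile 26.3 of random lists matched on expression, so a common factor and separate changes cannot be told apart by it. The T17 list exceeded the T cell receptor list by 0.02 in mean log2 change, though its median was higher, 0.34 against 0.21. The bootstrap 95% interval of the mean difference was -0.15 to 0.19, and permutation of list membership gave p = 0.77. That permutation reassigned genes, and with 2 libraries per genotype neither value measures the spread between libraries. Aire-/- replicate 1 had a higher B cell to CD3 ratio (0.985) than Aire+/+ replicate 2 (0.873) and still the higher T17 level (0.12 against -0.03). Its T cell receptor list was higher as well (0.12 against -0.10), and its 13 B cell genes were slightly lower (-0.07). This pair therefore does not separate a mixture from a change of the T17 program. A trend with transcript length and GC content was not the whole source, since the mean of the T17 list was 0.37 once it was removed and camera with its preset correlation called the list (adjusted p = 3.9e-05, against 0.49 with the estimated correlation and 0.20 without Aire+/+ replicate 1, both with the trend kept). A change of the T17 program with genotype stays open as untested.

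Cpm, at -1.86 (SE 0.24), lay below the mean of the B cell genes other than Igj less 3 SD (-1.31), though less than 1 SE below the lowest of them less 3 SD (-1.70). Aire-/- replicate 1 and Aire+/+ replicate 2 were the libraries of the 2 genotypes closest in these genes. Between them these B cell genes differed by -0.07 on average (less 3 SD, -0.87) and Cpm by -1.86. Cpm lay below such a bound in the other pairs too except Aire-/- replicate 2 against Aire+/+ replicate 1 (-1.80 against -1.86). A smaller share of the RNA that these B cell genes mark was therefore not the whole cause in the closest pair. Igj had 0 against 827 counts in that pair, so cells carrying Igj were not held equal. A changed share of such cells stays open for Cpm. Cpm and Aire share chromosome 10, so strain variants carried along with the Aire mutation are a possible explanation. Tested genes within 40 Mb of Aire had an unadjusted p under 0.05 in 17 of 328 cases (5.18%), against 528 of 9455 elsewhere (5.58%, 1-sided Fisher's exact p = 0.66). That window takes in Cpm itself, 39.6 Mb away, and a variant that alters 1 gene would hardly move this share. The test therefore cannot decide on strain variants at Cpm. A changed share of other cells, such as those of the macrophage list, was not tested for Cpm and stays open. With 1 gene in question and no sequence of these mice analysed here, variants at Cpm and an effect of Aire cannot be told apart either.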
